A study of Arabidopsis thaliana with 12 samples.

How the data were processed

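Gene expression was measured in stem fragments of Arabidopsis thaliana with Affymetrix ATH1 arrays hybridised with biotin-labelled aRNA. The 12 arrays form 4 groups of 3: wild type (Columbia) at the stem base, wox4-1 at the base, wild type in the first internode and wox4-1 in the first internode. The labels call each array a biological replicate and give 13 to 17 stems per pool. Plants grew for 3 weeks in short days (8 h light) and then in long days (16 h light). Stems were 15 to 20 cm tall and 49 to 58 days old, and only stems whose lowest internode reached 3.5 cm were taken. Fragments were 0.5 cm long and came from the base or, for the internode, from a point 1.5 to 2.0 cm over the top leaf of the rosette.

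The values are log2 expression values per probe set as deposited by the authors, who name RMA as the processing tool. RMA combines background correction, quantile normalization across arrays and a median polish over the probes of a set. Its version and the software that ran it are not given in the sources used here. Values were used on the deposited log2 scale without further scaling. The table holds 22810 probe sets on 12 arrays, and 64 control probe sets were set aside, leaving 22746 tested. Gene names came from the supplied probe table: 13513 probe sets carry 1 gene, 503 carry several and 8730 (38.4%) are unnamed here, which does not mean that they lack a gene. Of the probe sets with 1 gene, 13436 matched the reference gene table. No probe set carries the name WOX4, so the mutated gene was not analysed here. For arrays, the number of replicates limits the precision, and 3 per group were used.

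Comparisons were made with limma 3.58.1 in R 4.3.3. One linear model with a mean per group was fitted to all 12 arrays (lmFit), and the variances were moderated with eBayes without trend and without the robust option. The 6 contrasts were base over internode in wild type, base over internode in wox4-1, wox4-1 over wild type at the base, wox4-1 over wild type in the first internode, the difference between these genotype effects, and their average. Every p-value was adjusted by Benjamini-Hochberg over the 22746 probe sets of its contrast. A probe set was called at an adjusted p under 0.05, with no minimum fold change. Standard errors (SE) are the moderated ones of limma unless stated otherwise. Words such as rose and fell are used for called genes. In the genotype contrasts they mean higher or lower in wox4-1 than in wild type, and in the position contrasts higher or lower at the base than in the internode.

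Named genes were picked by a rule. In each contrast it takes WOX4, the 10 largest positive and the 10 largest negative log2 changes among called probe sets with 1 gene whose groups of arrays do not overlap, up to 4 called members of each gene list (or the 2 with the smallest p where none passed), the 5 genes with the smallest p where fewer than 5 passed, and the cambium markers measured by name, which were CLE41 and CLE44.

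Gene lists were tested with limma's camera, which asks whether a list moved relative to all other genes, with a preset correlation between genes of 0.01 and 1 probe set per gene (the one with the highest mean) over 13356 genes. The adjusted p of a list is over the lists of its family in 1 contrast. Of 25 lists fixed before the data were examined, 8 had at least 3 measured members: cambium regulators, cell division, secondary wall enzymes, lignin biosynthesis, photosynthesis, primary wall and elongation, auxin response, and reference genes. They are called fixed lists. Only 51 of the 404 genes on the fixed lists (12.6%) had a named probe set, and 10 fixed lists had no measured member. A family of 28 added lists was therefore drawn up once it was known which genes the annotation covers, but before any fit or gene value was known. Their names and results are given with the comparisons. Some genes are on lists of both families. Camera with a correlation estimated per list, and fry, which tests whether the genes of a list move on balance in 1 direction without comparing them with other genes, were run as alternatives.

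The fit was tested on simulated data with the same layout, in which 100 of 22746 probe sets were shifted by log2 0.5 and 100 by log2 1. At log2 1 the share called ranged from 71% for the difference between genotype effects to 98% for the average, with 88% to 95% in the other contrasts. At log2 0.5 these shares were 16%, 82% and 55% to 60%. All calls of shifted probe sets had the right sign, and 2 to 12 unchanged probe sets were called. A list shifted by log2 0.3 was called in all 6 contrasts, and no other of the 28 lists was. The simulated probe sets varied independently of each other, whereas the estimated correlation in the measured mitosis list was 0.272. The simulation therefore does not test how camera at the preset correlation treats lists whose genes vary together.

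Whether equal replicate numbers pair arrays was checked by correlating, across probe sets, the deviations of arrays from their group means. Genes are not independent replicates in such a correlation. Wild-type base and internode arrays of the same number correlated with r of 0.294 to 0.592, while wox4-1 base and internode arrays gave -0.05 to 0.24, and arrays of different genotypes -0.057 to 0.115. The numbers were not used as a block in the reported fits. Alternatives were quantile normalization again, centring each array on its median, a filter keeping probe sets with a log2 value of at least 6 on 3 or more arrays (11048 probe sets), eBayes with trend and robust, arrayWeights, only the groups of the contrast, a replicate block across the 4 groups, each array left out in turn, 1 probe set per gene, a fold minimum of 2 (log2 1), and an adjusted p threshold of 0.01. After the values were seen, 4 more were added: both wild-type replicate 2 arrays left out, a block within wild type, a block within each genotype, and the mean of both positions per genotype and replicate number. The fold minimum and the threshold of 0.01 were applied to counts and not to single genes, and the dim filter leaves out genes under its level. Left out of the text are chromosome positions, since no genome build is given for the array annotation. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.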

Results

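Transcript levels were measured in inflorescence stems of wild-type Arabidopsis and of wox4-1, a mutant of the homeobox gene WOX4. WOX4 is known as a regulator of the cambium, the layer of dividing cells that thickens the stem. Fragments from the stem base and from the first internode gave 4 groups of 3 arrays, each a biological replicate made from a pool of stems. Array medians lay between log2 5.56 and 5.71, all values between 2.29 and 13.60, and arrays of a group correlated with r of 0.992 to 0.997. No probe set carried the name WOX4 in the tables used here, so the level of the mutated gene is not reported here and gives no check of the genotype labels.

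Position in the stem was the main axis of variation. The first principal component held 53.4% of the variance and parted base arrays (-32.8 to -22.9) from internode arrays (21.4 to 30.3). The second held 16.0% and parted wild-type arrays (1.3 to 29.8) from wox4-1 arrays (-23.2 to -5.1). Along it, both wild-type replicate 2 arrays stood farthest out, at 29.8 at the base and 23.7 in the internode. On the array of wox4-1 internode replicate 2, the actin control had a log2 difference between its 3′ and 5′ probe sets of 2.26, against 1.22 to 1.51 on the other 11 arrays, and the GAPDH control 0.52, against at most 0.09. At the base the actin difference also moved with genotype, with 1.47 (SD 0.04, n = 3) in wild type and 1.29 (SD 0.06) in wox4-1, and the GAPDH difference was 0.03 (SD 0.11) and -0.12 (SD 0.07), and what this does to the genotype results at the base was not tested.

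**Figure D1:**
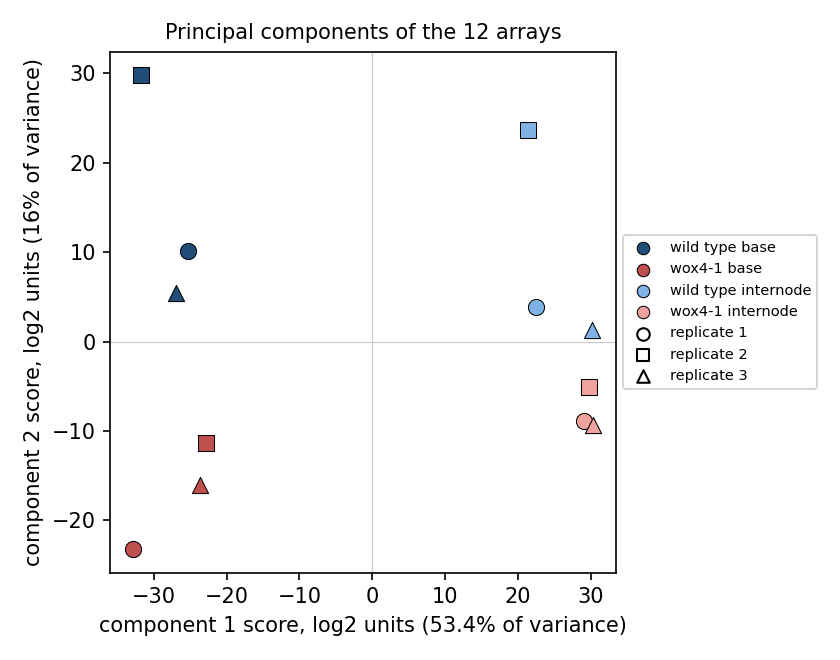
Scores of the 12 arrays on the first (x axis, 53.4% of variance) and second (y axis, 16.0%) principal components of log2 expression, with groups as colours and replicate numbers as markers. Base arrays lie between -32.8 and -22.9 and internode arrays between 21.4 and 30.3 on the x axis.

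The first comparison asked how the stem base differs from the first internode in wild type (3 arrays against 3). Genes of anthocyanin synthesis were among those with the largest rise at the base. DFR, which encodes dihydroflavonol reductase, rose at least 26.3-fold (log2 4.72, SE 0.17, limma adjusted p 1.76e-09), from a mean log2 of 3.95 to 8.67. AT1G62500, of the lipid transfer protein family, rose at least 66.4-fold (log2 6.05, SE 0.11, adjusted p 1.3e-12), and AT1G60590, of the pectin lyase-like family, at least 34.7-fold (log2 5.12, SE 0.12, adjusted p 1.15e-11). Their internode means of log2 3.35 and 3.59, like that of DFR, lie near the low end of the values, where arrays hardly tell levels apart. Changes of genes with 1 of the compared means at or under that of DFR (3.95) are therefore lower bounds in all comparisons, and their order is open. SP1L5, related to the microtubule protein SPIRAL1, fell by 3.78 on the log2 scale (SE 0.13, adjusted p 8.96e-10), and TRY, a repressor of trichome fate, fell at least 7.05-fold (SE 0.20 on the log2 scale, adjusted p 6.55e-07).

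Of the 22746 probe sets, 4485 were called in wild type, 2183 higher and 2302 lower at the base, and 493 of them changed at least 2-fold. Without both wild-type replicate 2 arrays 2435 were called. With each array centred on its median, 54.7% of calls were higher instead of 48.7%. The other 7 genes with the largest rises were AT1G09750, which encodes an aspartyl protease, AT1G10640, AT5G13140, AT2G28780, AT4G10270, AT3G61490 and AT4G14090, the locus of an anthocyanin glucosyltransferase, with log2 changes between 2.98 and 4.44, which are lower bounds for AT1G10640, AT2G28780 and AT3G61490. The other 8 with the largest falls were AT4G33666, AT3G28270, NdhL, AT1G35710, AT1G76960, AT1G13650, AT5G58980 and AT5G25560, with log2 changes between -2.93 and -2.16, which are lower bounds of the fall for NdhL and AT1G13650. All 20 remained called under every alternative fit. As a background, 9.4% of the 13356 genes with their own probe set were called higher and 8.4% lower.

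Among the added lists, flavonoid genes rose at the wild-type base: 5 of 8 members were called higher and none lower (median log2 0.64, camera adjusted p 5.7e-08, adjusted p = 0.0791 with an estimated correlation). Besides DFR these included UF3GT (log2 2.67, SE 0.18), AT5MAT (2.04, SE 0.15) and UGT78D2 (0.67, SE 0.10), all of which act on anthocyanins or flavonols. Cytosolic ribosomal proteins were higher in 66 of 108 members and lower in none, by a small amount each (median 0.30, camera adjusted p 2.19e-20, adjusted p = 0.191 with an estimated correlation), with AT4G39200 and AT5G67510 at the top, each by 0.50. The PYK10 complex, the proteins that gather around the beta-glucosidase of endoplasmic reticulum bodies, rose in 3 of 7 members (median 0.34, camera adjusted p 0.00492, adjusted p = 0.0909 with an estimated correlation), among them PYK10 (at least 0.87, SE 0.12) and JAL34 (0.76, SE 0.11). Of 31 genes of mitosis and DNA replication, 7 rose and none fell (median 0.20, camera adjusted p 0.0111, adjusted p = 0.549 with an estimated correlation), a list that did not pass with the dim filter (0.135) or without both wild-type replicate 2 arrays (0.0879). The largest of these rises were in AT3G02640 (0.70, SE 0.10), AT5G16250 (0.56, SE 0.09) and AT4G15830 (0.52, SE 0.09), which are on the list for known co-expression and are not characterised cell cycle proteins. The Aurora kinase gene AUR2 rose by 0.48 (SE 0.14, adjusted p 0.0237), a call that ended without wild-type base replicate 2 (adjusted p 0.11) or 3 (0.0627) and without wild-type internode replicate 2 (0.0682) or 3 (0.0776).

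Photosynthesis genes were lower at the wild-type base than in the internode. Nuclear photosynthesis and chlorophyll genes fell in 18 of 28 members and rose in none (median -0.41, camera adjusted p 1.65e-13, adjusted p = 0.0791 with an estimated correlation). NdhL fell at least 6.75-fold (SE 0.18 on the log2 scale, adjusted p 3.26e-07) and NdhN fell by 1.76 (SE 0.15), both subunits of the chloroplast NDH complex. Plastid-encoded photosynthesis genes fell in 18 of 47 members (median -0.39, camera adjusted p 4.67e-10, adjusted p = 0.191 with an estimated correlation), among them psbK (-0.88, SE 0.11) and ndhJ (-0.85, SE 0.14). All 4 members of the fixed photosynthesis list fell, also when adjusted over the list alone: SBPASE by log2 -1.20, PRK by -0.98 and RCA by -0.78 of carbon fixation, and LHCB4.1 of light harvesting by -0.49 (camera adjusted p 2.12e-06, adjusted p = 0.0951 with an estimated correlation). Secondary wall co-expressed genes fell in 8 of 17 members (median -0.26, camera adjusted p 6.1e-06, adjusted p = 0.191 with an estimated correlation), the most in AT1G56720 (-0.96, SE 0.11).

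On the fixed cambium list 2 of 5 genes rose at the wild-type base, also 2 when adjusted over the list alone (camera adjusted p 0.887). MOL1, a receptor-like kinase gene known to restrain the cambium, rose by 0.62 (SE 0.11, adjusted p 0.00159). CLE41, which encodes the TDIF peptide, a signal to the cambium, rose by 0.27 (SE 0.09, adjusted p 0.0486), and CLE44, for the same peptide, was not called (-0.19, SE 0.11, adjusted p 0.286). The CLE41 call was lost without any single 1 of 8 arrays, namely wild-type base 1, 2 or 3, wild-type internode 1 or 2, wox4-1 base 2, and wox4-1 internode 1 or 3, with adjusted p from 0.0555 to 0.158. Adjusted over the list alone, 2 of 4 cell division genes rose, 2 of 3 secondary wall enzymes fell (1 over all genes), 1 of 5 lignin biosynthesis genes fell, 1 of 6 primary wall and elongation genes rose and 1 fell, 1 of 8 auxin response genes rose and 1 fell, and none of 3 reference genes changed. The auxin response calls were WES1, which encodes an enzyme that conjugates auxin (1.75, SE 0.10), and IAA29 (-0.78, SE 0.17). Camera did not call these 6 lists, with adjusted p of 0.178, 0.153, 0.328, 0.948, 0.954 and 0.954.

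The other added lists did not pass as lists in wild type, although single members did. UGT glycosyltransferases rose in 10 of 47 and fell in 2 (camera adjusted p 0.0535), with UGT71C1 up by 1.39 (SE 0.14). Histones rose in 3 of 8 (0.0535), HTB2 by 0.59, and tubulins in 3 of 7 (0.0863), TUB5 by 0.80 and TUB1 by 0.73. SWEET sugar transporters fell in 3 of 15 (0.0863): SWEET13 by log2 -2.08, SWEET11 by -1.31 and SWEET2 by -0.57. Epidermis and stomata genes fell in 2 of 7 (0.0863) and jasmonate genes rose in 3 of 7 (0.0879), the defensin gene PDF1.2b by 2.84 (SE 0.55). Class III peroxidases rose in 3 of 33 and fell in 2 (0.8), with AT3G21770 up by 1.65 and AT5G64120 down by log2 -1.85. Meristem and lateral organ genes rose in 2 of 15 (PTL by 1.71 and SHI by 0.76) and fell in 1 (0.556). Monolignol and lignin genes rose in 1 of 12 and fell in 2 (0.468), and BGLU45, for a glucosidase of monolignols, fell by 1.50 (SE 0.11). The TBL wall acetylation family rose in 4 of 22 and fell in 2 (0.975), expansins in 2 and 1 of 18 (0.953), GH9 glucanases in 1 and 2 of 15 (0.498), and xyloglucan enzymes in 0 and 2 of 15 (0.416). Calcium and early stress genes rose in 1 of 15 and fell in 2 (0.498), senescence genes in 1 and 3 of 7 (0.41), auxin genes in 1 and 1 of 20 (0.8), and GSTU glutathione transferases in 1 and 1 of 11 (0.498). Cold and dehydration genes rose in 1 of 11 (0.8) and plastid-encoded gene expression genes in 1 of 20 (0.818). No member of the cytokinin response regulators (6 genes, 0.498) or of the flower and pollen genes (14 genes, 0.8) was called. Median, mean and camera direction had 1 sign in every called list, and differed for the uncalled cambium, primary wall, auxin response, reference, TBL, monolignol, expansin and auxin gene lists.

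The same question was asked of wox4-1 stems (3 arrays against 3). DFR rose at least 34.6-fold at the base (log2 5.11, SE 0.17, limma adjusted p 1.09e-09), and AT1G62500 at least 57.9-fold (log2 5.86, SE 0.11, adjusted p 2.03e-12). AT3G28270 fell 12.1-fold (SE 0.49 on the log2 scale, adjusted p 0.000146) and SP1L5 fell 11.8-fold (SE 0.13, adjusted p 1.51e-09). In all, 5564 probe sets were called, 2602 higher and 2962 lower, and 568 changed at least 2-fold. With each array centred on its median, 67.5% of 7022 calls were higher, against 46.8% as deposited, so the balance between higher and lower depends on the scaling. Among 13356 genes, 11.4% were called higher and 11.2% lower.

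Wild type and wox4-1 shared most of this axis: 1419 probe sets were higher in both genotypes (249.7 by chance) and 1748 lower (299.8 by chance), while 5 were called in opposite directions. Of the wild-type calls, 97.4% had the same sign in wox4-1, with a slope of 0.922. The other 8 of the 10 largest rises in wox4-1 were in AT1G09750, AT1G60590, AT1G10640, AT5G13140, AT4G14090, AT4G10270, UF3GT and AT5G45950 (log2 between 2.79 and 4.55), and the other 8 largest falls in AT5G58980, AT2G25590, AT5G25560, AT4G33666, AT1G65370, TRY, AT1G76960 and AT1G35710 (-2.95 to -2.42). The changes of AT1G60590, AT1G10640, AT4G10270 and TRY are lower bounds. All 20 remained called under every alternative fit.

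In wox4-1, flavonoid genes rose in 5 of 8 members (median 0.58, camera adjusted p 1.33e-06, adjusted p = 0.112 with an estimated correlation). Cytosolic ribosomal proteins rose in 51 of 108 (median 0.24, camera adjusted p 1.66e-11, adjusted p = 0.434 with an estimated correlation), and the PYK10 complex in 4 of 7 (median 0.36, camera adjusted p 0.00648, adjusted p = 0.112 with an estimated correlation). UGT glycosyltransferases rose in 12 of 47 and fell in 1 (median 0.15, camera adjusted p 0.0113, adjusted p = 0.434 with an estimated correlation), and did not pass with the dim filter (0.052). Tubulins rose in 3 of 7 (median 0.13, camera adjusted p 0.0492, adjusted p = 0.247 with an estimated correlation), TUB1 by 1.37 (SE 0.08) and TUB5 by 0.97 (SE 0.09). The call of the tubulins list was lost without wox4-1 internode replicate 2 (adjusted p 0.0597), without both wild-type replicate 2 arrays (0.0576), with median centring (0.0527), with the dim filter (0.0571) and with a block across groups (0.0659). Nuclear photosynthesis genes fell in 15 of 28 (median -0.32, camera adjusted p 3.77e-10, adjusted p = 0.112 with an estimated correlation), and plastid-encoded photosynthesis genes in 17 of 47 (median -0.24, camera adjusted p 0.000146, adjusted p = 0.434 with an estimated correlation). The 4 genes of the fixed photosynthesis list all fell, also when adjusted over the list alone (camera adjusted p 3.62e-05, adjusted p = 0.163 with an estimated correlation). Secondary wall co-expressed genes fell in 4 of 17 and rose in 1 (median -0.21, camera adjusted p 0.00609, adjusted p = 0.481 with an estimated correlation), and did not pass with the dim filter (0.0571). Genes of mitosis and DNA replication rose in 7 of 31 and fell in 2, and the list did not pass (camera adjusted p 0.508).

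Single genes of other lists moved with position in wox4-1 too. Expansins rose in 6 of 18 (camera adjusted p 0.101), EXPB3 by 0.74 (SE 0.13), and ARR15, a cytokinin response regulator gene, rose by 0.65 (SE 0.12). GH3.17, for an auxin-conjugating enzyme, rose by at least 0.80 (SE 0.15), CML42 by 0.81 (SE 0.14) and GH9B13 by 1.38 (SE 0.17). MOL1 rose by 0.51 (SE 0.11) and CLE41 by 0.32 (SE 0.09, adjusted p 0.0194), a call that ended without wox4-1 base 1 (adjusted p 0.0665) and without wox4-1 internode 1 (0.0533) or 3 (0.0785). CLE44 was not called (0.17, SE 0.11, adjusted p 0.292). Adjusted over the list alone, 2 of 5 cambium regulators, 2 of 4 cell division genes, 1 of 6 primary wall genes and 4 of 8 auxin response genes rose, 2 auxin response genes and 1 of 5 lignin genes fell, and no secondary wall enzyme or reference gene changed. In no called list did median, mean and camera direction differ in sign. They differed for the uncalled secondary wall enzymes, monolignol, xyloglucan, SWEET and GSTU lists.

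The central comparison was wox4-1 against wild type at the stem base (3 arrays against 3), where the loss of a cambium regulator was examined in the older part of the stem. AT2G10940, of the lipid transfer protein family, rose 4.27-fold (SE 0.28 on the log2 scale, limma adjusted p 0.00141), and AT5G63180, of the pectin lyase-like family, 2.61-fold (log2 1.39, SE 0.10, adjusted p 5.01e-05). The beta-tubulin gene TUB1 rose 2.01-fold (SE 0.08, adjusted p 6.59e-05) and YUC6, which encodes an enzyme of auxin synthesis, 1.70-fold (log2 0.77, SE 0.11, adjusted p 0.00221). AT1G54020, which encodes a GDSL-type lipase, fell by 1.99 on the log2 scale (SE 0.29, adjusted p 0.00205). JAL23, for a jacalin-related lectin of the PYK10 complex, fell by 1.21 (SE 0.14, adjusted p 0.000481), from a mean log2 of 9.72 to 8.51.

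At the base 1146 probe sets were called between genotypes, 574 higher and 572 lower in wox4-1, and 66 of them changed at least 2-fold. With each array centred on its median, 72.4% of 1378 calls were higher, against 50.1% as deposited, so the balance of directions depends on the scaling. The count was 548, 342 and 650 without wild-type base replicate 1, 2 and 3, and 609 without wox4-1 base replicate 3. Without both wild-type replicate 2 arrays it was 282, with 24.4% of the 1146 calls kept, and with only the groups of the contrast 403, with 33.9% kept. Among 13356 genes, 2.3% were called higher and 2.2% lower, and the median size of the called changes was log2 0.49. The other largest rises were in AT3G46880, AT5G48490, AT1G12845, GLC, AT2G47010, AT5G35740, AT2G18480 and AT5G45670 (log2 1.45 down to 1.07). Further large falls were in AT2G28780, AT2G43670, AT4G30830, AT1G60590, AT1G64370, AT4G29700, AT3G11930 and AT4G27450 (-1.40 to -1.02). The changes of AT5G45670 and AT2G43670 are lower bounds. Of these 20 genes AT3G11930, for a universal stress protein, was not called without wild-type base replicate 2 (adjusted p 0.062) or wox4-1 base replicate 3 (0.0514).

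Genes of mitosis and DNA replication were lower in wox4-1 at the base: 10 of 31 fell and none rose (median -0.35, camera adjusted p 1.13e-12, adjusted p = 0.231 with an estimated correlation). The mean of the list was log2 5.53 ± 0.10 (SD, n = 3) in wild type and 5.20 ± 0.11 in wox4-1. AT1G72250, a kinesin gene, fell by 0.70 (SE 0.17, adjusted p 0.0334), a call that ended without wild-type base replicate 2 (adjusted p 0.129) or 3 (0.101) and without wox4-1 base replicate 1 (0.0751) or 3 (0.108). The fixed cell division list passed (median -0.33, camera adjusted p 0.0202, adjusted p = 0.199 with an estimated correlation) with 1 of 4 genes lower, and 2 lower when adjusted over the list alone. It shares genes such as AUR2 with the mitosis list, so it is not separate support. Without wox4-1 base replicate 1 the adjusted p of the cell division list was 0.0578.

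Lists of nuclear photosynthesis, secondary wall and expansin genes went the other way. The plastid-encoded photosynthesis genes (camera adjusted p 0.287) and the fixed photosynthesis list (0.068) did not pass. Nuclear photosynthesis and chlorophyll genes rose in 5 of 28 members and fell in none (median 0.20, camera adjusted p 2.15e-05, adjusted p = 0.231 with an estimated correlation). Secondary wall co-expressed genes rose in 2 of 17 (median 0.23, camera adjusted p 0.000224, adjusted p = 0.277 with an estimated correlation). The fixed secondary wall enzymes rose in 1 of 3, IRX15-L, which acts in xylan deposition, and in 3 when adjusted over the list alone (median 0.38, camera adjusted p 0.0162, adjusted p = 0.274 with an estimated correlation). The IRX15-L call (0.38, SE 0.09, adjusted p 0.0281) ended without wild-type base replicate 1 (0.0778), 2 (0.0681) or 3 (0.0886) and without wox4-1 base replicate 1 (0.0677) or 3 (0.0647). Expansins rose in 3 of 18 (median 0.18, camera adjusted p 0.014, adjusted p = 0.231 with an estimated correlation), the most in EXPA15 (0.70, SE 0.12, adjusted p 0.00635). Cytosolic ribosomal proteins were lower as a list (median -0.12, camera adjusted p 1.04e-10, adjusted p = 0.332 with an estimated correlation) with 1 of 108 called. The jasmonate genes were lower as a list (median -0.28, camera adjusted p 0.012, adjusted p = 0.231 with an estimated correlation) with 1 of 7 called, and did not pass with the dim filter (0.0713).

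CLE44 rose 1.40-fold in wox4-1 at the base, from a mean log2 of 6.23 to 6.71 (SE 0.11, adjusted p 0.0275), while CLE41 was not called (0.13, SE 0.09, adjusted p 0.433). The CLE44 call ended without wild-type base replicate 1 (adjusted p 0.0583), 2 (0.0806) or 3 (0.0909) and without wox4-1 base replicate 1 (0.065). Adjusted over the list alone, 1 of 5 cambium regulators, 3 of 8 auxin response genes, 1 of 4 photosynthesis genes, 1 of 5 lignin genes and 1 of 6 primary wall genes rose, and no reference gene changed. Of the other lists, none passed. BGLU46, for a glucosidase of monolignols, fell by log2 -0.59 (SE 0.09, adjusted p 0.00281), SWEET2 rose by 0.61 (SE 0.12, adjusted p 0.0113) and TBL38 by 0.60 (SE 0.11, adjusted p 0.00716). No flavonoid gene was called between genotypes, DFR included (0.29, SE 0.17, adjusted p 0.347). Median, mean and camera direction differed in sign for the monolignol, SWEET and GSTU lists.

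In the first internode wox4-1 and wild type differed at fewer probe sets (3 arrays against 3). AT5G63180 rose 1.92-fold (log2 0.94, SE 0.10, limma adjusted p 0.00355). AT1G54020 fell by 2.58 on the log2 scale (SE 0.29, adjusted p 0.00355), AT2G34810, of the berberine bridge enzyme-like family, fell 2.86-fold (SE 0.18 on the log2 scale, adjusted p 0.00355), and JAL23 fell by 1.13 (SE 0.14, adjusted p 0.00406). AT5G07030, which encodes an aspartyl protease, rose by 1.06 (SE 0.15, adjusted p 0.0103), a call that ended without wild-type internode replicate 1 (adjusted p 0.0629). YUC6 rose by 0.67 (SE 0.11, adjusted p 0.0276), and was not called without wild-type internode replicate 1 (0.136) or 2 (0.101) or wox4-1 internode replicate 1 (0.108), 2 (0.0571) or 3 (0.12).

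The internode comparison called 55 probe sets, 25 higher and 30 lower, and 12 changed at least 2-fold. The count was 22 and 20 without wild-type internode replicate 1 and 2, 28, 30 and 20 without wox4-1 internode replicate 1, 2 and 3, and 110 without wox4-1 base replicate 1. It was 25 without both wild-type replicate 2 arrays (34.5% of the 55 calls kept) and 182 with arrayWeights. AT1G59930 rose by 0.74 (SE 0.09), AT5G44400 by 0.64 (SE 0.08) and AT1G25230 by 0.62 (SE 0.08). These genes and AT5G63180, AT1G54020, AT2G34810 and JAL23 remained called under every alternative fit that tested them (the dim filter left out AT2G34810), and the other 13 of the 20 genes with the largest rises and falls did not. Among the latter, GID1A, which encodes a gibberellin receptor, fell by 0.73 (SE 0.12, adjusted p 0.0233), a call that ended without wild-type internode replicate 1 (0.127) or 2 (0.0642) or wox4-1 internode replicate 1 (0.0713), 2 (0.0982) or 3 (0.0785).

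Both genotype comparisons overlapped: 17 probe sets were higher in wox4-1 at both positions (0.6 by chance) and 26 lower (0.8 by chance), with none in opposite directions. The chance counts take both comparisons as independent. Wild-type arrays of equal number correlate between positions, so some overlap and equal signs can arise without a genotype effect. All 55 internode calls had the same sign at the base, and 1010 of the 1146 base calls (88.1%) had the same sign in the internode. Across all probe sets the genotype changes at base and internode correlated with r = 0.511. With wild-type arrays of different numbers for each position the r was 0.288 to 0.363. Those versions use fewer wild-type arrays, and the added noise lowers r by itself. Their covariance was 0.0133 to 0.0186, against 0.02 over all arrays.

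**Figure D2:**
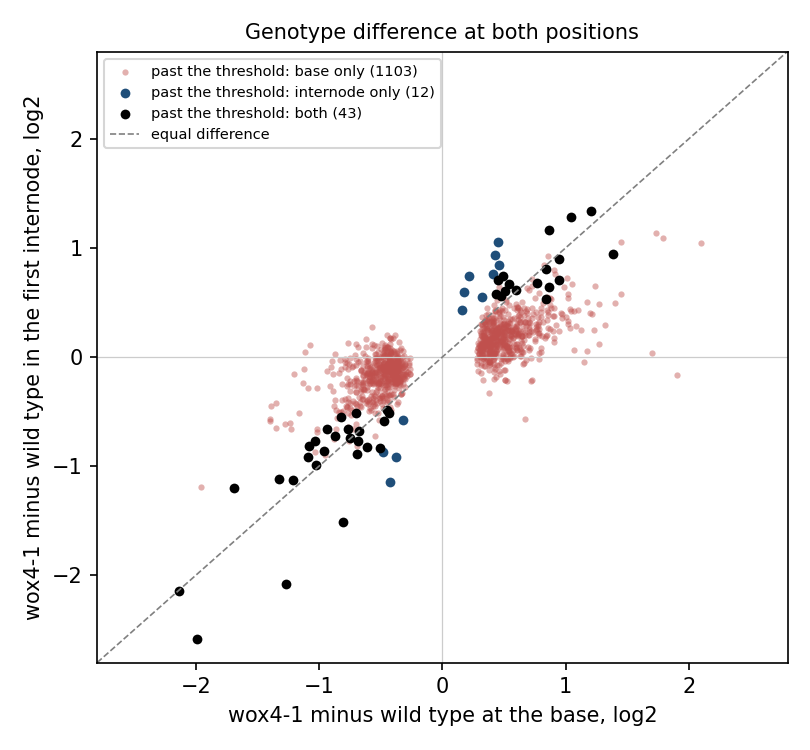
Log2 change in wox4-1 over wild type at the base (x axis) and in the first internode (y axis) for probe sets called at either position. Colours show where a probe set was called (1103 at the base alone, 12 in the internode alone, 43 in both). The dashed line marks equal change, and uncalled probe sets are not drawn. Groups have 3 arrays each, and all 55 internode calls have the same sign at the base.

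Mitosis and DNA replication genes were also lower in wox4-1 in the internode, with 2 of 31 called, AT4G15830 and AT5G16250 (median -0.21, camera adjusted p 1.87e-13, adjusted p = 0.494 with an estimated correlation). Both are on the list for known co-expression and are not characterised cell cycle proteins. With fry none of the lists called in this comparison passed (mitosis adjusted p 0.112). The list mean was log2 5.35 ± 0.08 (SD, n = 3) in wild type and 5.11 ± 0.09 in wox4-1. The AT4G15830 call (-0.52, SE 0.09, adjusted p 0.0382) ended without any 1 of 8 arrays (wild-type internode 1, 2 or 3, wox4-1 internode 1 or 3, wild-type base 2, and wox4-1 base 2 or 3, with adjusted p from 0.0511 to 0.183). The fixed cell division list was lower (median -0.15, camera adjusted p 0.0419, adjusted p = 0.203 with an estimated correlation) with none called over all genes and 1 lower when adjusted over the list alone, and without wox4-1 base replicate 1 the list did not pass (0.0803). AUR2 was lower by log2 -0.69 without passing (SE 0.14, adjusted p 0.0609). Nuclear photosynthesis genes were higher as a list with no member called (median 0.11, camera adjusted p 0.000266, adjusted p = 0.538 with an estimated correlation), as were secondary wall co-expressed genes (median 0.11, camera adjusted p 0.0127, adjusted p = 0.746 with an estimated correlation), a list that did not pass without both wild-type replicate 2 arrays (0.399). Cytosolic ribosomal proteins were lower as a list with no member called (median -0.07, camera adjusted p 5.66e-08, adjusted p = 0.746 with an estimated correlation). Cold and dehydration genes were lower (median -0.28, camera adjusted p 0.00462, adjusted p = 0.732 with an estimated correlation), and did not pass without both wild-type replicate 2 arrays (0.428), on which 4 of the 11 genes were high. Adjusted over the list alone, 2 of 8 auxin response genes rose, and no gene of the other 6 fixed lists changed. CLE44 (0.12, SE 0.11, adjusted p 0.877) and CLE41 (0.08, SE 0.09, adjusted p 0.906) were not called. Signs of median, mean and camera direction differed for the lignin, primary wall, auxin response and GSTU lists.

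**Figure D3:**
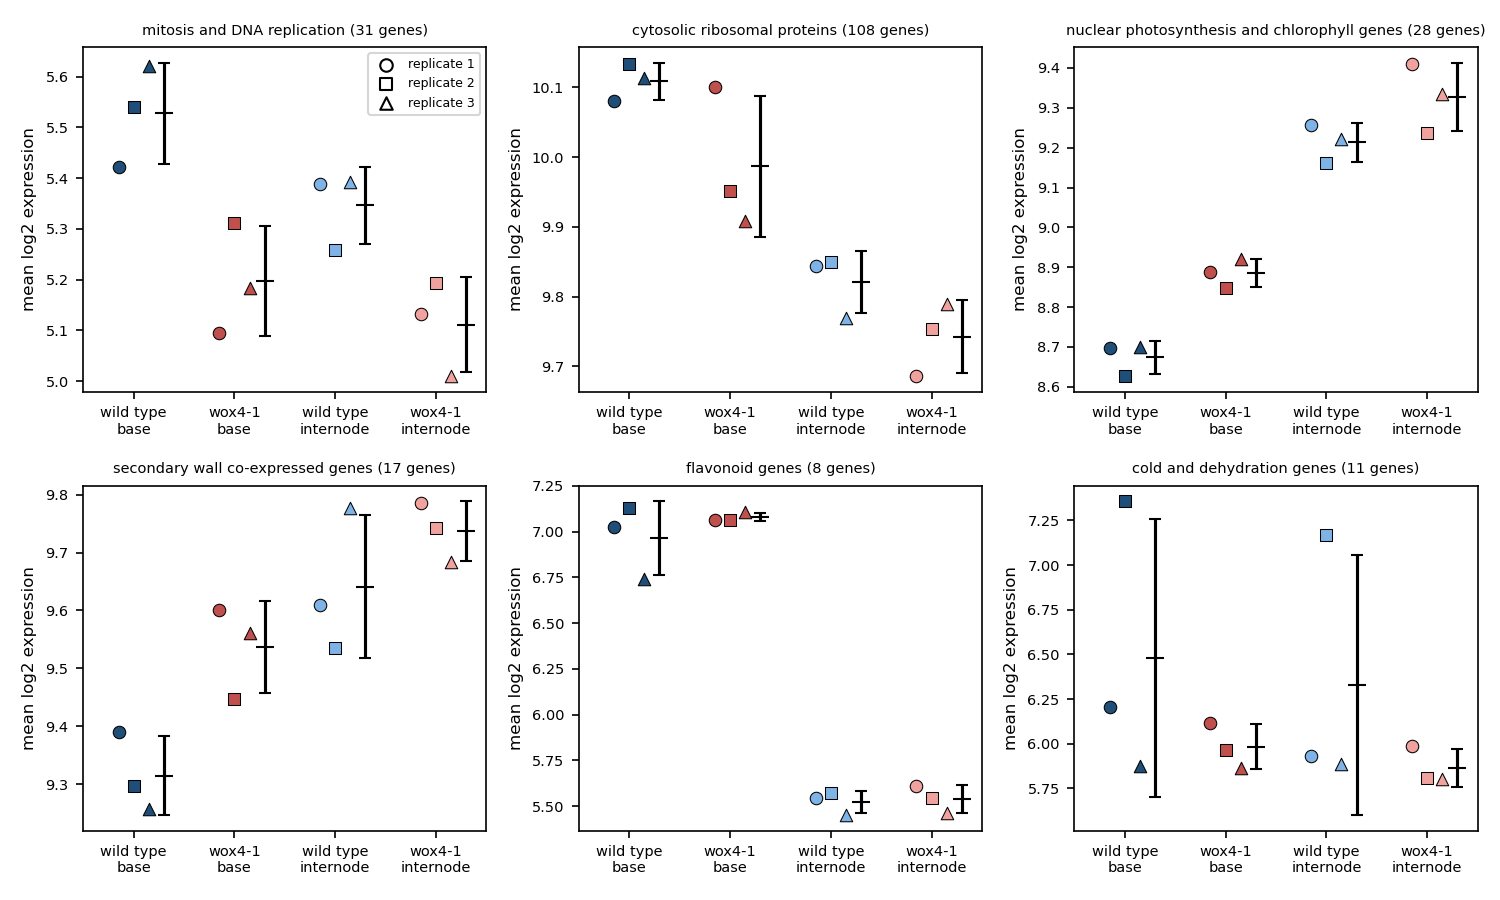
Mean log2 expression (y axis) of 6 gene lists on each of the 12 arrays (points, in 4 groups on the x axis), with bars for the mean ± SD of 3 arrays per group. The mitosis list has means of 5.53 and 5.20 at the base and 5.35 and 5.11 in the internode, for wild type and wox4-1.

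Averaged over both positions, wox4-1 and wild type were compared as 6 arrays against 6, which asks for the mean of the genotype effects at base and internode. A large effect at 1 position alone can pass, so a call does not show an effect at both. Called singly at both positions were 43 probe sets. AT5G63180 rose 2.24-fold (log2 1.16, SE 0.07, limma adjusted p 5.97e-06), TUB1 by 0.69 (SE 0.06, adjusted p 4.62e-05), YUC6 by 0.72 (SE 0.08, adjusted p 0.000285) and the zinc finger gene IDD16 by 0.83 (SE 0.10, adjusted p 0.000577). AT1G54020 fell 4.87-fold (log2 -2.28, SE 0.20, adjusted p 7.29e-05) and JAL23 2.25-fold (log2 -1.17, SE 0.10, adjusted p 4.31e-05). HIS1-3, a linker histone gene induced by drought, fell by 1.51 (SE 0.36, adjusted p 0.0283), a call that ended without wild-type base replicate 1 or 2, wild-type internode replicate 1 or 2, wox4-1 base replicate 3, and wox4-1 internode replicate 1 or 3 (adjusted p from 0.0562 to 0.0707).

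The average called 1292 probe sets, 657 higher and 635 lower, 25 of them by at least 2-fold. With each array centred on its median, 66.3% of 1409 calls were higher, against 50.9% as deposited. The count was 753 without wild-type base replicate 2, 851 and 823 without wild-type internode replicate 1 and 2, and 780 without wox4-1 internode replicate 1. Without both wild-type replicate 2 arrays it was 482, with 35.7% of the 1292 calls kept, and with arrayWeights 2118. No label says that equal replicate numbers are 1 pool. The wox4-1 arrays of number 1, 2 and 3 correlated between positions with r of 0.136, 0.24 and -0.05, which neither shows nor excludes pairing. When base and internode arrays of equal replicate number were averaged first, 3 means against 3, 592 were called. Of the calls of genes picked by the naming rule 36 held in this form and 23 did not, among them HIS1-3 (adjusted p 0.102), CLE44 (0.0831), CHLI2 (0.0587) and AT3G54400 (0.055), and the lists were not refitted this way. The other largest rises were in AT2G10940, AT3G46880, AT1G06830, AT2G19970, P1R1, AT3G54400, AT5G48490 and AT2G47010 (log2 1.57 down to 0.80), and further falls in AT2G34810, AT4G29700, AT3G11930, AT4G22212, AT4G27450, AT4G30830 and AT1G31040 (-1.16 to -0.80). The changes of P1R1, AT5G48490, AT2G47010 and AT4G30830 are lower bounds.

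Mitosis and DNA replication genes fell on average in 12 of 31 members and rose in none (median -0.26, camera adjusted p 2.96e-17, adjusted p = 0.22 with an estimated correlation), while 2.6% of all genes rose and 2.5% fell. Under every alternative fit that tested them (the dim filter left out AUR2) the calls of the chromosomal protein gene 3xHMG-box2 (-0.61, SE 0.12, adjusted p 0.00899), AUR2 (SE 0.10, adjusted p 0.00617, mean log2 5.68 and 5.30 at the base and 5.19 and 4.50 in the internode for wild type and wox4-1) and AT4G15830 (-0.47, SE 0.07, adjusted p 0.00113) remained. The fixed cell division list was lower (median -0.22, camera adjusted p 0.0081, adjusted p = 0.0966 with an estimated correlation), with AUR2 called and 2 of 4 lower when adjusted over the list alone. Cytosolic ribosomal proteins fell in 10 of 108 (median -0.10, camera adjusted p 2.07e-13, adjusted p = 0.328 with an estimated correlation). The jasmonate genes were lower, with 1 of 7 called (median -0.12, camera adjusted p 0.0452, adjusted p = 0.22 with an estimated correlation), a list that did not pass without wox4-1 base replicate 1 (0.0773), without both wild-type replicate 2 arrays (0.0805) or with the dim filter (0.135). Cold and dehydration genes were lower with none called (median -0.27, camera adjusted p 0.0117, adjusted p = 0.333 with an estimated correlation), and did not pass without both wild-type replicate 2 arrays (0.282) or with the dim filter (0.093).

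Nuclear photosynthesis genes rose on average in 5 of 28 (median 0.15, camera adjusted p 7.6e-07, adjusted p = 0.22 with an estimated correlation), with CHLI2, of chlorophyll synthesis, up by 0.35 (SE 0.07, adjusted p 0.0105). The fixed photosynthesis list was higher with 1 of 4 called, also 1 when adjusted over the list alone (median 0.12, camera adjusted p 0.0352, adjusted p = 0.315 with an estimated correlation), and did not pass without both wild-type replicate 2 arrays (0.114). Secondary wall co-expressed genes rose in 1 of 17 (median 0.14, camera adjusted p 5.83e-05, adjusted p = 0.328 with an estimated correlation) and the fixed secondary wall enzymes in 1 of 3, or 3 when adjusted over the list alone (median 0.25, camera adjusted p 0.0113, adjusted p = 0.305 with an estimated correlation). The epidermis and stomata genes rose in 2 of 7, among them BLT by 0.39 (median 0.10, camera adjusted p 0.0452, adjusted p = 0.22 with an estimated correlation), a list that did not pass without wox4-1 base replicate 1 (0.0773), without both wild-type replicate 2 arrays (0.0636), with median centring (0.0569) or with a block across groups (0.0515). CLE44 rose by 0.30 (SE 0.08, adjusted p 0.0401), a call that ended without wild-type base 1, 2 or 3, wox4-1 base 1, wild-type internode 1 or 2, or wox4-1 internode 1 or 2 (adjusted p from 0.0521 to 0.0958), and CLE41 was not called (0.10, SE 0.06, adjusted p 0.389). UGT71C1 fell by 0.64 (SE 0.10, adjusted p 0.00272). Adjusted over the list alone, 1 of 5 cambium regulators rose and 1 fell, 2 of 8 auxin response genes rose and 1 fell, 1 of 5 lignin genes and 1 of 6 primary wall genes rose, and no reference gene changed. Signs of median, mean and camera direction differed for the cambium, lignin, monolignol, primary wall, SWEET, plastid-encoded photosynthesis, calcium, GSTU and UGT lists.

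Whether the genotype effect differs between base and internode was tested directly as the difference of both effects. A single probe set of 22746, unnamed here, was called by limma, with 1827 at an unadjusted p under 0.05. Its log2 change in wox4-1 was 2.07 larger at the base than in the internode (SE 0.23, adjusted p 0.00912), where its values lay near the low end on all 6 arrays, so no effect there is not told from no measurable signal. None of the named genes passed. The 5 with the smallest p were AT1G62770 (1.23, SE 0.17), AT1G60590 (-1.16, SE 0.17), AT5G45670 (1.00, SE 0.15) and AT1G12845 (1.15, SE 0.18), each with an adjusted p of 0.07, and BGLU33 (-0.90, SE 0.16, adjusted p 0.169), and AT1G60590 and AT5G45670 were near the low end in the internode too. TUB1 (0.64, SE 0.12, adjusted p 0.169), CLE44 (0.36, SE 0.16, adjusted p 0.604) and CLE41 (0.05, SE 0.12, adjusted p 0.944) did not pass either. The larger number of genotype calls at the base is thus not matched by a tested difference at single named genes. This contrast called 16% of simulated changes of log2 0.5, against 55% for genotype at the base. Every simulated contrast held the same number of changed probe sets, so its adjusted threshold was not that of the measured data. With 1 measured call here, against 1146 at the base, the share found may be lower than 16%. Differences of log2 0.5 can therefore be missed, and the result does not show that the genotype effects are equal. The count of 1 was 3 without wild-type base replicate 1 or 3 or wox4-1 base replicate 1 or 3, 2 without wild-type internode replicate 3, and 0 without wox4-1 internode replicate 2 or 3.

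Among the added lists, 6 differed in their genotype effect between positions at the preset correlation, and none with an estimated one. Expansins (median difference 0.24, camera adjusted p 0.0168, adjusted p = 0.23 with an estimated correlation), SWEET sugar transporters (0.18, camera adjusted p 0.0332, adjusted p = 0.23 with an estimated correlation), auxin genes (0.11, camera adjusted p 0.0405, adjusted p = 0.251 with an estimated correlation) and plastid-encoded photosynthesis genes (0.10, camera adjusted p 0.0332, adjusted p = 0.715 with an estimated correlation) were more positive at the base. Jasmonate genes (-0.23, camera adjusted p 0.0488, adjusted p = 0.251 with an estimated correlation) and cytosolic ribosomal proteins (-0.06, camera adjusted p 0.0399, adjusted p = 0.758 with an estimated correlation) were more negative. Without wox4-1 base replicate 1 the jasmonate genes did not pass (0.0892), nor with the dim filter (0.138). With median centring the SWEET sugar transporters, auxin genes, plastid-encoded photosynthesis genes and jasmonate genes (each 0.0603) and the cytosolic ribosomal proteins (0.073) did not pass. The ribosomal proteins also ended with the dim filter (0.193), and the auxin genes without both wild-type replicate 2 arrays (0.0955). No member of these 6 lists was called singly. Of the fixed lists none passed, and adjusted over the list alone 1 primary wall gene and 2 auxin response genes had a positive difference and 1 auxin response gene a negative one. Signs of median, mean and camera direction differed for the reference, cold and dehydration, and GSTU lists. Over all 6 comparisons, none of the 47 list calls held with an estimated correlation.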

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

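In the mitosis pattern the test without pool 2, and in the pool 2 pattern the tests of a single faulty array and of water or cold stress, were chosen after the result was seen. The difference of genotype effects between positions rested on 1 probe set, unnamed here, whose log2 difference was 2.07 (SE 0.23, limma adjusted p 0.00912). It rose in wox4-1 at the base by 1.90 (SE 0.16, adjusted p 7.87e-05) and was not called in the internode (-0.17, SE 0.16, adjusted p 0.886). Its values were 3.91, 4.55 and 3.97 on the wild-type base arrays against 6.08, 5.97 and 6.10 in wox4-1. In the internode they were 3.29, 3.68 and 3.23 against 3.39, 3.08 and 3.24, near the low end of the values, so the size of the difference is open and no effect in the internode is not told from no measurable signal there. The gene behind it is not analysed here and the cause was not tested.

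Gene lists with a difference between positions at the preset correlation were small in size and none passed with an estimated correlation. Expansins differed by a median of 0.24 (camera adjusted p 0.0168, adjusted p = 0.23 with an estimated correlation), with 0.18 at the base and -0.04 in the internode. SWEET sugar transporters differed by 0.18 (0.0332, adjusted p = 0.23 with an estimated correlation), auxin genes by 0.11 (0.0405, adjusted p = 0.251 with an estimated correlation) and plastid-encoded photosynthesis genes by 0.10 (0.0332, adjusted p = 0.715 with an estimated correlation). Jasmonate genes differed by -0.23 (0.0488, adjusted p = 0.251 with an estimated correlation) and cytosolic ribosomal proteins by -0.057 (0.0399, adjusted p = 0.758 with an estimated correlation). The medians at base and internode were -0.28 and -0.11 for jasmonate genes, which did not pass in the internode (0.685), and -0.12 and -0.07 for ribosomal proteins.

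Genes of mitosis and DNA replication were lower in wox4-1 at both positions, by a mean of -0.283 (SE 0.055). Without pool 2 of wild type the mean was -0.302 (SE 0.065), which speaks against that pool alone carrying it. Both SE come from an ordinary linear model of the list means per array, not from limma. That model takes arrays as independent, though wild-type arrays of equal number correlate, so these SE may be too small. Against a general shift of dim probe sets, the median of -0.256 lay at percentile 0.01 of 10000 lists matched for level, the smallest they can give (95% of them between -0.043 and 0.061). This speaks only against a shift of all genes at that level. The random lists lack the correlation between mitosis genes (estimated at 0.272), so the percentile is no separate support for the list. For a shift along the stem axis, the slope of -0.104 over all other genes and the position mean of 0.181 predict -0.019. Error in the position change pulls that slope towards 0, both changes share wild-type arrays, and the slope need not hold for this list. The prediction therefore speaks only against a shift of the size this slope gives, and a larger one is left open. Lower cell division in wox4-1 stems may lie behind this and stays a hypothesis, and a smaller share of dividing cells was not tested. In the average the list did not pass camera with an estimated correlation (adjusted p = 0.22), and in the internode it did not pass fry (adjusted p 0.112). The histone list did not pass between genotypes (camera adjusted p 0.155 at the base, 0.685 in the internode and 0.239 in the average).

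The genotype change at the base ran against the position change, as if the wox4-1 base were shifted towards the internode, with a slope of -0.145 over all arrays. With arrays not shared between both changes the slopes were -0.131, -0.072 and -0.064, the weakest being -0.064, so shared arrays alone do not make it, and in the internode they were -0.059, -0.043 and -0.117. Of 568 probe sets changed at least 2-fold along wox4-1 stems, 43.1% shifted this way at the base. That share met the bound set for rejecting fragments taken higher in wox4-1, but the bound was poorly designed, because picking these probe sets by wox4-1 position reuses the wox4-1 base arrays and lowers the share. Shares from separate arrays, added after the result was seen, were 65.6%, 59.8% and 62.3% at the base and 58.3%, 59.8% and 73.1% in the internode, of 477, 612 and 711 probe sets, so fragments taken higher cannot be told from a biological shift here.

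On both wild-type replicate 2 arrays the mean of the cold and dehydration genes was raised by 1.32 at the base and 1.26 in the internode, the largest of 36 lists. This came from 4 of 11 members, LEA4-5 (at least 5.25 and 4.43 log2 units above the other wild-type pools), LTI30 (4.19 and 3.18), COR15A (2.07 and 3.00) and DI21 (1.59 and 1.86), while the others lay between -0.13 and 0.48 at the base and -0.05 and 0.57 in the internode. Outside the list, 44 probe sets picked for a 4-fold raise on the base array had a median raise of 2.434 (lower quartile 1.906) on the internode array, and 41 picked on the internode array 2.891 at the base, which speaks against 1 faulty array, and a score of 0.985 (1.054 at the base) on the genotype difference over 482 probe sets, where 1 is wild type and 0 is wox4-1, speaks against a swapped genotype label. At both positions 35 probe sets were raised at least 4-fold and 77 at least 2-fold, against 0 and at most 2 in any other pool. That contrast is partly built in, since wild-type pools 1 and 3 were compared with a mean that includes replicate 2. The wox4-1 arrays of equal number, counted as pools here, showed no clear pairing, which does not exclude it. Some of these genes, such as AT4G33550, were also higher on wild-type base replicate 1 than on base replicate 3, while others, such as AT3G02480, were not. Water or cold stress of that pool could give such a raise but could not be told from another cause. Without both arrays the cold and dehydration list no longer passed in the average of genotypes (adjusted p 0.282).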

How the results depend on the processing

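Leaving out both wild-type replicate 2 arrays, the blocks within wild type and within each genotype, the mean of both positions per replicate number, and the list fits without wox4-1 base 1 or wox4-1 internode 2 were chosen after the result was seen. Of 344 calls of named genes 207 held in every alternative fit that tested them and 137 were lost in at least 1, and none turned direction. The dim filter tested 259 of them, and the fold minimum and the threshold of 0.01 were applied to counts alone. Of 47 list calls, 13 were lost with fry. Among them were all list calls between genotypes in the internode. Their fry adjusted p was 0.112 for mitosis, 0.139 for cell division, 0.304 for nuclear photosynthesis, and 0.619 for secondary wall co-expressed, cold and dehydration, and ribosomal genes. With 1 probe set per gene, the lower counts mostly reflect probe sets that were not tested. Of 2384, 3012, 598, 27 and 677 main calls tested this way, 2354, 2985, 595, 26 and 669 held. The order is position in wild type and in wox4-1, genotype at the base and in the internode, and the average. The cause of the other moved counts was not tested.

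For base over internode in wild type, 4485 calls became 2354 with 1 probe set per gene, 2435 without both wild-type replicate 2 arrays, 493 with a fold minimum of 2, 2520 at 0.01, and 4392 with a block within wild type. Leaving out 1 array gave 3122 to 5350. For base over internode in wox4-1, 5564 became 2990, 568 and 3052 for 1 probe set per gene, the fold minimum and 0.01, and 4163 to 5650 with 1 array left out.

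The count for wox4-1 over wild type at the base, 1146, became 403 with only the groups of the contrast, 600 with 1 probe set per gene, 282 without both wild-type replicate 2 arrays, 66 with the fold minimum and 274 at 0.01. Leaving out wild-type base 1, 2 or 3 gave 548, 342 or 650, wox4-1 base 3 gave 609, and wox4-1 base 2 gave 1459, the highest. In the internode, 55 became 88 with trend and robust, 182 with arrayWeights, 26, 25, 12 and 14. These are 1 probe set per gene, both wild-type replicate 2 arrays out, the fold minimum and 0.01. Without wox4-1 base 1 it was 110, and without wild-type internode 1 or 2, or wox4-1 internode 1, 2 or 3, it was 22, 20, 28, 30 and 20.

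The count for wox4-1 over wild type averaged over both positions, 1292, became 2118 with arrayWeights, 676 with 1 probe set per gene, 482 without both wild-type replicate 2 arrays, 592 as means per replicate number, 25 with the fold minimum and 457 at 0.01. Without wild-type base 2, wild-type internode 1 or 2, or wox4-1 internode 1, it was 753, 851, 823 and 780, and without wox4-1 base 1 it was 1428, the highest. The single call of the difference of effects became 2 with quantile normalization again, 7 with median centring or with trend and robust, 5 with arrayWeights or a block within each genotype and 3 with a block across groups. Its probe set was not among those tested with the dim filter, which called 0, or with 1 probe set per gene, which called 4 others. Without single arrays it was 0 to 3.

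Some list calls ended in other alternatives, by adjusted p. Mitosis in wild-type position ended with the dim filter (0.135) and without both wild-type replicate 2 arrays (0.0879). The tubulins ended under 5 alternatives (0.0527 to 0.0659), and UGT glycosyltransferases (0.052) and secondary wall co-expressed genes in wox4-1 (0.0571) with the dim filter. The jasmonate genes ended with the dim filter at the base (0.0713), in the average (0.135) and in the difference (0.138). Without both wild-type replicate 2 arrays, secondary wall co-expressed genes (0.399) and cold and dehydration genes (0.428) ended in the internode, and fixed photosynthesis (0.114), jasmonate (0.0805), cold and dehydration (0.282) and epidermis and stomata genes (0.0636) in the average. Median centring ended plastid-encoded photosynthesis, auxin, jasmonate and SWEET (each 0.0603) and ribosomal genes (0.073) in the difference, and epidermis (0.0569) in the average.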

Other observations

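The splits that keep replicate numbers whole were chosen after the result was seen. A single probe set for 25S ribosomal RNA, an array control left out of the comparisons, differed in level between groups. Its mean was log2 9.84 (SD 0.05, n = 3) in wild-type base, 9.13 (SD 0.19) in wox4-1 base, 8.88 (SD 0.19) in wild-type internode and 8.20 (SD 0.18) in wox4-1 internode. Cytosolic ribosomal protein genes had the same order of groups, with list means of 10.11, 9.99, 9.82 and 9.74. What moves the 25S signal was not tested.

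Some genes that rose along the stem moved between genotypes as well. AT1G60590 rose at least 34.7-fold at the wild-type base and at least 15.5-fold in wox4-1, and fell by 1.11 in wox4-1 at the base. TUB1 rose towards the base by 0.73 in wild type and by 1.37 in wox4-1, though the difference did not pass (limma adjusted p 0.169). UGT71C1 rose towards the base by 1.39 in wild type and 1.57 in wox4-1, and fell in wox4-1 by 0.64 in the average of both positions.

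Relabelling arrays between groups asks whether chance alone could give as many calls. For position, the real labels ranked 1 of 10 splits in wild type (4485 calls, highest other 10) and 1 of 10 in wox4-1 (5564, highest other 0). For genotype they ranked 1 of 10 at the base (1146, highest other 0) and 1 of 10 in the internode (55, highest other 0). With 10 splits a value under 0.05 cannot be reached. For the average, base and internode arrays of equal number were kept together, because the wild-type arrays correlate by number, and the real labels ranked 1 of 10 splits (1292 calls, highest other 1), again too few for a value under 0.05. Splits of single arrays gave 508 calls at most in 100, but they break those pairs. For the difference of effects, splits of this kind also ranked the real labels 1 of 10 (1 call, highest other 0), too few as well. Its splits of single arrays (11 of 100 with as many calls, at most 128) do not test it, since 9 of the 10 others with calls kept the base groups whole and with them the base genotype effect.

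Quality differed between single arrays. The array weight of wox4-1 base replicate 1 was 0.29 and that of wox4-1 internode replicate 2 was 0.66, against 0.83 to 1.50 on the others. The latter also had the actin 3′ to 5′ difference of 2.26. Without wox4-1 base replicate 1 the genotype counts were 881 at the base (653 of the 1146 shared), 110 in the internode and 1428 in the average. Without wox4-1 internode replicate 2 they were 1118, 30 and 1247.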
